A study of Mus musculus with 3 samples.

How the data were processed

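The samples were 3 ribosomal RNA-depleted total RNA libraries from the chromatin fraction of C57BL/6J bone marrow-derived macrophages, all of 1 condition. Per the labels, each was a separate biological replicate with 1 technical replicate. They do not say whether each came from a different animal, so the SD values measure only the spread between these samples, which may be technical. The labels give a size range of 250 to 400 for each library.

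For each library the authors deposited a gene table and a transcript table with estimated (expected) counts and TPM, which per the file headers have the columns that RSEM writes, and a further transcript table with estimated counts and TPM in the columns that kallisto writes. Per the deposited notes that accompany the tables, the build is mm10 with GENCODE M21, the first pair of tables derives from an alignment to the transcriptome and the last was made from the reads directly. Program versions and settings, and whether counting used strand, are not given in the sources used here, so reads of overlapping genes on opposite strands and of near-identical genes may be split wrongly. The first quantification is called alignment-based and the other read-based. TPM values as deposited are relative abundances that sum to the same total over all rows of a library, so a few abundant short RNAs lower every other value.

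Gene rows numbered 81881, of which 55536 matched the GENCODE M21 annotation by identifier. A further 26248 had a numeric identifier and 97 were spike-in rows. These were left out of gene counts and normalisation, but stay in the totals behind class shares and the depths given. Numeric rows held 39, 22 and 18 counts in replicates 1, 2 and 3. The alignment-based table held 168207 transcripts, of which 141862 matched the annotation, and the read-based table held 141864. Symbols, gene types, isoform types and positions come from that annotation. Where 2 identifiers share a symbol, the one with more counts was used. Gapdh and Pgk1 stand in both the glycolysis and the housekeeping list, and Cd14 in both the macrophage and the Toll-like receptor 4 list.

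The choices, gene lists, markers and alternatives were fixed before the data were examined, unless stated. A gene counted as expressed at a TPM of at least 1 in all 3 libraries. List levels are medians of log2(TPM + 0.1) over members in each library, with their percentile among 10000 random lists of the same size. Random lists were drawn from expressed protein-coding genes together with the members of the list itself. Unexpressed members stay in the list median, while the median gene is taken over expressed genes and random lists hold nearly only such genes. Lists with many unexpressed members thus lie low by construction. A fold against the median gene on this scale understates differences of low genes. List differences were taken within each library and tested with an exact two-sided sign-flip test, which cannot go below p = 0.25 with 3 libraries. Percentiles describe these libraries and are not p-values, since genes are not replicates.

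Expected counts were rounded to whole numbers for edgeR, with TMM normalisation, genes of at least 10 counts in all libraries and an intercept-only design. Replicate variability is the SD over libraries of log2(CPM + 0.5), set against 10000 random lists matched on mean expression in 20 bins. The share of isoforms with a retained intron was computed per expressed protein-coding gene with such an isoform, for lists with at least 3 of them. A first run required 5, which left out cytokines, and the minimum was lowered after that run so that all the lists of a written prediction could be tested. Named genes are, per list, the 3 highest and the lowest by mean TPM, 17 genes fixed by name, the 20 highest protein-coding and 5 highest long noncoding genes with an effective length of at least 200 bases, the 10 protein-coding genes of highest SD among those of at least 10 CPM, and the highest 2 markers of each cell type. Some genes that this rule picks are not reported here.

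Alternatives covered TPM thresholds of 0.5 and 5, pseudocounts of 0.01 and 1, expressed members only, TPM rescaled over genes of effective length of at least 200 without mitochondrial, numeric and spike-in rows, CPM in place of TPM, means over members, the read-based values, DESeq2 size factors, no count filter, a prior count of 2, shares of TPM, and leaving out each replicate. A run over protein-coding genes only and one without the ribosomal RNA locus of chromosome 17 were added after the data were seen.

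The code was tested on simulated data. For replicate agreement over 13301 genes, counts drawn with a biological coefficient of variation of 0.2 gave back 0.217. In that simulation, 100% of genes raised 4-fold and 51% of those raised 2-fold in 1 library fell in the top 5% of SD. For list percentiles over 10000 simulated genes, 40 of 40 lists of doubled SD and 34 of 40 lists raised 4-fold fell in the top 2.5%. Of 40 unchanged lists, 4 and 2 fell in the top or bottom 2.5%. Noise was drawn independently for each gene, so this simulation does not cover lists whose members shift together in 1 library. Depth limits single values: intervals and floors (3 counts where a count is 0) cover counting error only, at 95% confidence by Wilson's method for shares, because reads without molecular identifiers are not independent molecules.

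Tools were R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.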

Results

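RNA held on chromatin was sequenced from bone marrow-derived macrophages of C57BL/6J mice, cells grown in culture from marrow progenitors. The cells received 100 ng/ml Lipid A, the part of bacterial lipopolysaccharide that activates Toll-like receptor 4, for 12 h. They were washed free of it for 12 h and received 100 ng/ml Lipid A again for 120 min. The chromatin fraction is enriched in RNA that is still being made or has not left the nucleus, and ribosomal RNA was depleted before sequencing. The 3 libraries were biological replicates of this 1 condition, with RNA inputs of 1 µg, 250 ng and 500 ng for replicates 1, 2 and 3. Repeated exposure of this kind is commonly used to study endotoxin tolerance. Cells left untreated or stimulated once were not analysed here, so each value below is a level and none is a response to Lipid A. Total expected counts were 10293545, 17820066 and 17548564 in replicates 1, 2 and 3. Gene values are TPM (length-scaled transcript abundance), given as mean ± SD over n = 3 libraries, and positions are on mouse build mm10.

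Interferon-stimulated genes, the antiviral genes driven by type I interferon, stood at the highest level of the 15 gene lists. All 26 members reached a TPM of at least 1 in every library, and all 26 lay above the median expressed protein-coding gene in every library. Their median was 7.40 ± 0.06 (SD, n = 3) on the log2(TPM + 0.1) scale, 14.1-fold above that median gene, whose level was 12.0 TPM. The list lay above 100% of 10000 random lists of expressed genes in each library. Mx1, an antiviral GTPase (ENSMUSG00000000386.15, chromosome 16, 97447035 to 97462907), had a TPM of 1001 ± 240.0. Oasl2 stood at 816 ± 25.6 and Rsad2, which encodes viperin, at 654 ± 144. The lowest member was Isg20 at 22.0 ± 9.91.

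Negative regulators and subunits of the NF-kB and Toll-like receptor pathways came next, though with expressed members only nuclear long noncoding RNAs, at 6.20, and host defence genes, at 6.05, lay above them. All 24 were expressed, 22 of them above the median gene in every library, and their median of 5.89 ± 0.29 (log2, SD, n = 3) was 4.96-fold above it. Between 99.99% and 100% of random lists lay lower, depending on the library. Tnip3, which encodes a partner of the deubiquitinase A20, had a TPM of 563 ± 62.8, Nfkb1 had 399 ± 22.8 and Traf1 had 291 ± 14.97. Nfkbia, the gene of the NF-kB inhibitor IkB-alpha (ENSMUSG00000021025.8), stood at 291 ± 37.4 and Tnfaip3, which encodes A20, at 203 ± 49.5. Socs3 reached 64.9 ± 23.9 and Irak3, a kinase-like inhibitor of receptor signalling, 62.8 ± 23.4. Socs1 was lowest at 4.51 ± 1.51.

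Cytokine genes spread over a wide range. Of 18 genes, 14 were expressed and 8 lay above the median gene in every library. The list median of 3.52 ± 0.33 (log2, SD, n = 3) was 0.960 times that of the median gene, and between 16.3% and 71.5% of random lists lay lower. With expressed members only, the list lay at 4.96, above the median gene at 3.58. Tnf (ENSMUSG00000024401.14) led with a TPM of 439.6 ± 23.8, followed by Il27 at 98.6 ± 25.3 and Il15 at 94.1 ± 18.7. Il1b stood at 54.6 ± 9.07, Il12b at 13.6 ± 3.48 and Il6 at 9.90 ± 2.40. The anti-inflammatory Il10 stood at 4.46 ± 0.45 and Ifnb1, the interferon-beta gene, at 3.17 ± 0.97. Il23a, Csf2, Csf3 and Lif did not reach a TPM of 1 in every library, and Lif was lowest at 0.057 ± 0.067.

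Chemokine genes ran from some of the highest to undetected. Of 18 genes, 13 were expressed and 9 exceeded the median gene in every library, with a list median of 4.26 ± 0.42 (log2, SD, n = 3). Between 66.1% and 98.5% of random lists lay lower, and expressed members alone had a median of 5.57. Ccl5 (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518) had a TPM of 1300.4 ± 148, Cxcl10 had 276 ± 62.0 and Ccl4 had 193 ± 66.6. Ccl17 had 0 counts in each library, which at 3 counts allows a share of up to 2.9e-05% in replicate 1. Cxcl1 and Ccl22, picked after their values were seen, were highest in replicate 3, at 20.6 against 5.10 and 6.20 for Cxcl1 and at 4.20 against 0.71 and 0.43 for Ccl22.

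Host defence and effector genes ranged from highly represented to nearly absent. Of 21 genes, 15 were expressed and 13 exceeded the median gene in every library, with a list median of 5.03 ± 0.56 (log2, SD, n = 3). Between 88.0% and 99.99% of random lists lay lower, and expressed members alone had a median of 6.05. Acod1, which makes the antibacterial metabolite itaconate (ENSMUSG00000022126.6, chromosome 14, 103046977 to 103056573), had a TPM of 924 ± 146. The acute-phase gene Saa3 stood at 452 ± 162 and the C-type lectin gene Clec4e at 370.2 ± 73.9. Nos2, the inducible nitric oxide synthase, had 40.4, 16.5 and 58.9 in replicates 1 to 3. Lcn2, which encodes an iron-scavenging protein, stood at 3.44 ± 1.19. Mmp9 was lowest, with 2 counts in replicate 2 and 0 in the others.

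**Figure D1:**
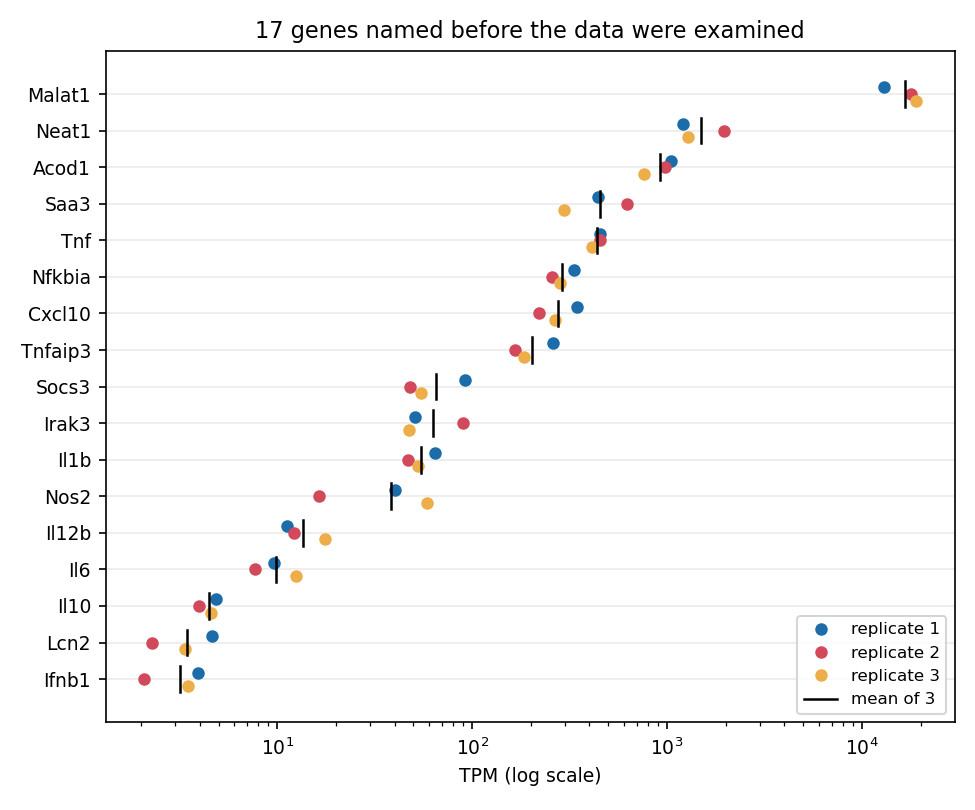
TPM on a log axis for 17 genes named before the data were examined, with 1 point per replicate and a bar at the mean of 3 libraries. Malat1 lies above 10000 TPM in each library, and Acod1, Saa3 and Tnf lie well above Il6, Il10 and Ifnb1.

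Immediate early genes, the transcription factor and regulator genes that respond first and briefly to stimulation, were low. Of 19 genes, 14 were expressed but only 4 exceeded the median gene in every library. The list median was 2.25 ± 0.49 (log2, SD, n = 3), 0.397 times the median gene, and between 0.01% and 6.78% of random lists lay lower. With expressed members only it was 3.17, against 3.58 for the median gene. Klf6 was highest with a TPM of 158 ± 17.7, followed by Junb at 62.2 ± 2.38 and Atf3 at 34.2 ± 3.29. Fosb stood at 0.11 ± 0.079.

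The order of these lists was compared within each library. The cytokine median lay below that of the feedback regulators by -2.37 ± 0.51 log2 units (SD, n = 3), and immediate early genes lay below the same regulators by -3.64 ± 0.46. Relative to cytokines, interferon-stimulated genes stood 3.88 ± 0.38 log2 units higher, host defence genes 1.503 ± 0.36 and chemokines 0.74 ± 0.10. Nuclear long noncoding RNAs stood 0.19 ± 0.07 log2 units above housekeeping genes. Each of these 6 differences had the same sign in 3 of 3 libraries, and the exact two-sided sign-flip test gave p = 0.25 for each, the smallest value that n = 3 allows. All 6 p-values being 0.25, Benjamini-Hochberg adjustment leaves them at 0.25. The excess of chemokines over cytokines ended at -0.016 when CPM (counts scaled to library size) replaced TPM, and that of nuclear RNAs over housekeeping genes became -0.20 with means over members. With expressed members only, cytokines lay -0.93 from the regulators, interferon-stimulated genes 2.44 above cytokines and nuclear RNAs 1.06 above housekeeping genes, and with means over members host defence genes stood 0.69 above cytokines.

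**Figure D2:**
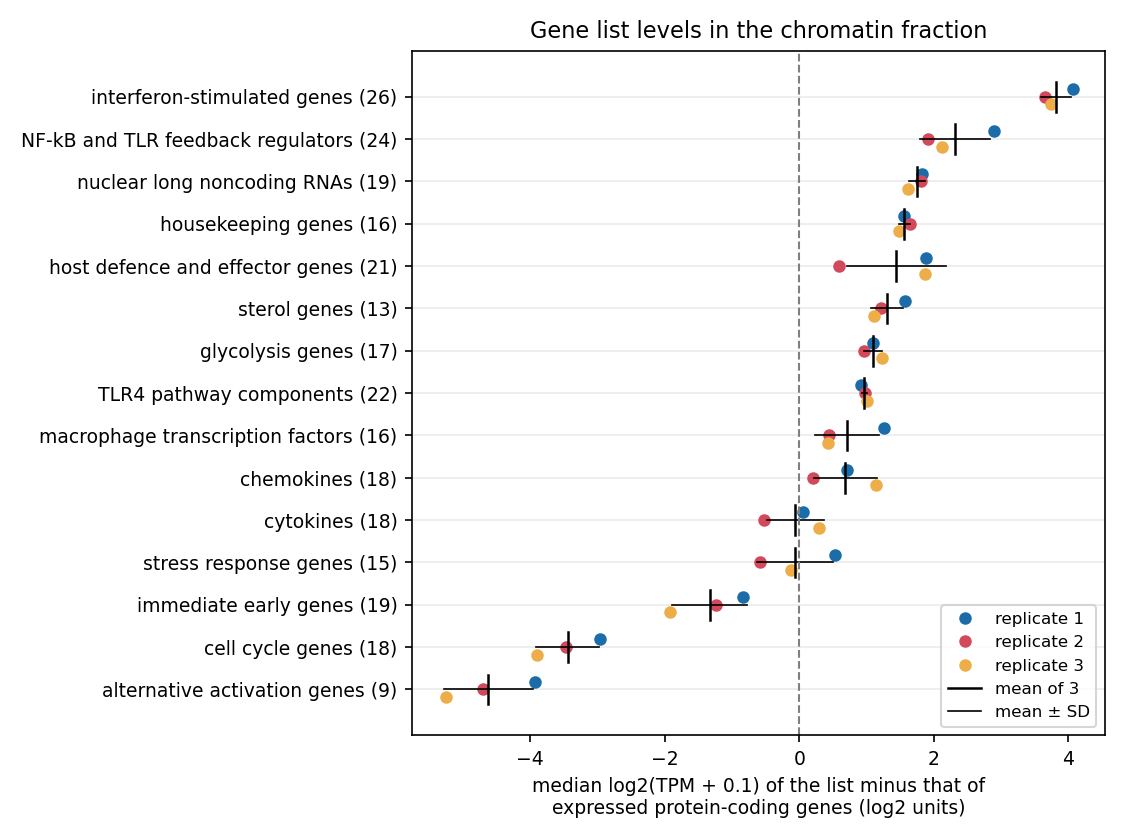
Median log2(TPM + 0.1) of each of 15 gene lists minus that of expressed protein-coding genes in the same library, with the number of measured members in brackets. Points are the 3 replicates, the upright bar is their mean and the line is mean ± SD. Interferon-stimulated genes lie 3.82 log2 units above the dashed line of the median gene and alternative activation genes lie at -4.62.

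Lists outside the inflammatory response described the cell state. Of 22 components of the Toll-like receptor 4 pathway, 21 were expressed, led by Irak2 at 207 ± 42.7, Ikbkb at 174 ± 20.99 and Tbk1 at 151 ± 38.2, with Lbp lowest at 0.06 ± 0.079. Tlr4 itself, outside the naming rule, stood at 4.94 ± 0.82. Among 16 macrophage transcription factors, 14 were expressed. Zeb2 had a TPM of 1104 ± 93.7, Batf 98.7 ± 18.03, Spi1, which encodes PU.1, 93.7 ± 48.3, and Irf4 0.38 ± 0.23. Genes of alternative activation, the state driven by interleukin 4, had the lowest list median, -1.04 ± 0.54 (log2, SD, n = 3), because most members were not expressed, and expressed members alone had a median of 3.54. Only Il4ra at 47.0 ± 2.87, Mrc1 at 12.1 ± 4.54 and Pparg at 1.57 ± 0.12 of its 9 members were expressed, and Retnla and Mgl2 had 0 counts in each library.

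Cell cycle genes were also low, with 7 of 18 expressed, and with expressed members only they were the lowest list, at 1.96. Mki67 at 18.7 ± 3.24, Pcna at 18.5 ± 0.97 and Tyms at 4.40 ± 0.99 were highest, and Plk1 stood at 0.17 ± 0.015. All 17 glycolysis genes were expressed, led by Pfkp at 108 ± 12.7, Pkm at 74.0 ± 9.16 and Pfkfb3 at 53.4 ± 12.9, with the glucose transporter gene Slc2a1 at 3.33 ± 0.77. Of 13 sterol genes, 12 were expressed. Nr1h3, the gene of the oxysterol receptor LXR-alpha, stood at 102 ± 27.1, the cholesterol exporter gene Abca1 at 88.9 ± 32.1 and Ch25h at 0.51 ± 0.19. Of 15 stress response genes, 13 were expressed, with Gadd45b at 170.1 ± 7.60, Mdm2 at 135 ± 27.4, Txnrd1 at 76.8 ± 10.1 and Nqo1 at 0.13 ± 0.07. All 16 housekeeping genes were expressed, with Actb at 670.0 ± 156, Eef1a1 at 199 ± 34.9 and B2m at 121 ± 22.9.

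Across all annotated genes, 12031 of 55536 reached a TPM of at least 1 in all 3 libraries. They included 9245 of 22028 protein-coding genes and 1094 of 10155 long noncoding RNA genes. The 20 protein-coding genes of highest mean TPM held several of immune function. Lilrb4a, an inhibitory leukocyte receptor gene (ENSMUSG00000112148.1, chromosome 10, 51490956 to 51496611), led with 2059 ± 97.7. Its neighbour Lilr4b had 1229 ± 279, and the split of reads between these similar genes is uncertain. Ikbke, a kinase gene of interferon induction (ENSMUSG00000042349.13), stood at 1840.1 ± 296, Tnfaip2 at 1711 ± 279, the class I antigen-presentation gene H2-K1 at 1696 ± 464 and Malt1 at 1232 ± 179. Tcirg1, Fth1, Fyb, Rsrp1, Rnf213, Parp14, Syk and Zc3h7a lay between 700.0 and 1267, as did Zeb2, Mx1, Acod1, Oasl2 and Adgre1. Ccl5 completed the 20 genes.

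By class, protein-coding genes other than those of histones, ribosomal proteins and mitochondria held 66.7% ± 3.34 (SD, n = 3) of expected counts. Long noncoding RNA genes held 26.9% ± 5.08, small noncoding RNA genes 2.10% ± 1.23, ribosomal protein genes 0.15% ± 0.013 and mitochondrial genes 0.057% ± 0.00028. Histone cluster genes held 0.0065% ± 0.00092. The mitochondrial share may be too low. In replicates 1, 2 and 3 mt-Atp6, picked after its values were seen, had 0.01, 0 and 0 counts. Its read-based TPM was 49.5, 45.1 and 49.2. Malat1, a nuclear-retained RNA (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672), held 9.05% ± 1.10 of counts alone. Gm26917 (ENSMUSG00000097971.3, chromosome 17, 39843013 to 39846341), annotated as a long intergenic noncoding RNA, held 12.5% ± 3.33. It lies beside Gm42418 (39846958 to 39848788), which overlaps the annotated ribosomal RNA gene CT010467.1 (39846353 to 39848827) on the opposite strand. Together these 3 genes held 9.90%, 15.6% and 18.2% of counts in replicates 1, 2 and 3. Without them, a check added after the data were seen, long noncoding RNA genes held 15.1% ± 1.92 and protein-coding genes 78.0% ± 0.42.

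On the TPM scale the same libraries looked different, because short genes are divided by a small effective length. Small noncoding RNA genes held 57.4% ± 6.78 of TPM and protein-coding genes 29.1% ± 3.15. Rmrp, the RNA of RNase MRP, held 9.73% ± 3.54 of TPM and 0.70% ± 0.23 of counts. The small nucleolar RNA gene Gm22988 held 7.09% ± 2.05 of TPM with a mean effective length of 7.16 bases, and both were picked after their values were seen. Of 19 nuclear long noncoding RNAs, 16 were expressed. Malat1 had a TPM of 16587 ± 3134, Neat1, the scaffold of paraspeckles, 1485 ± 416, and Xist, the RNA that coats the inactive X chromosome, 762 ± 169. Tsix was lowest at 0.073 ± 0.084.

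**Figure D3:**
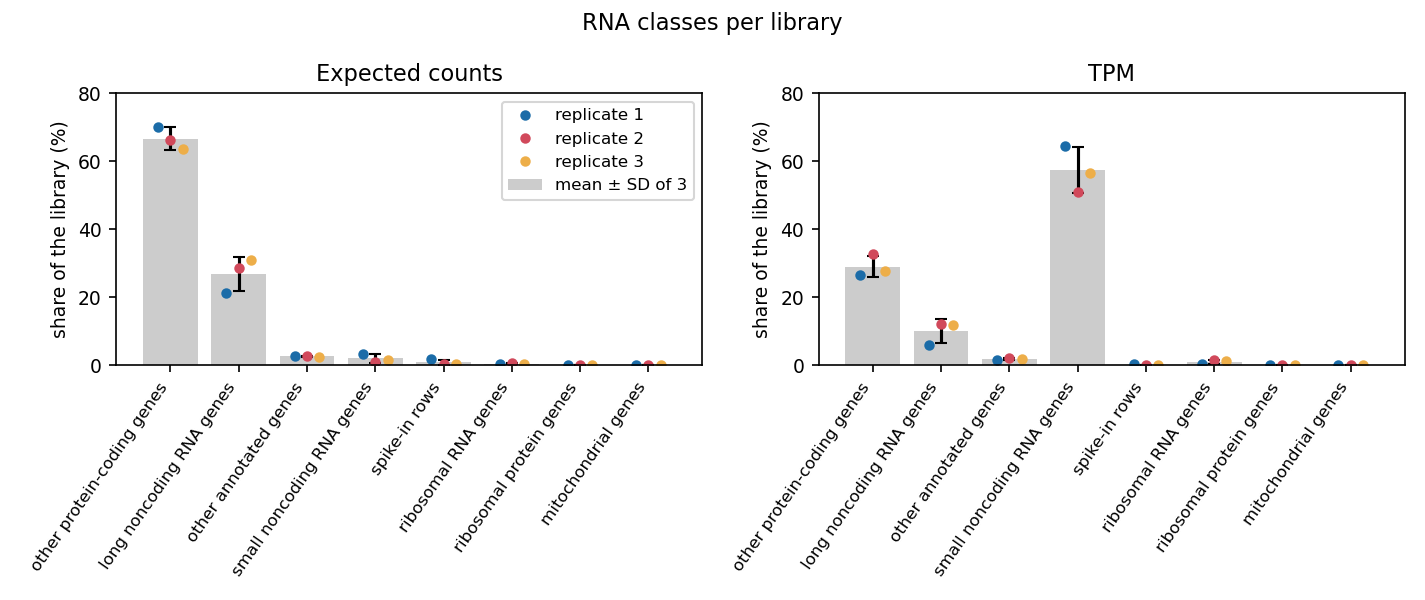
Share of each library in 8 classes of rows, in percent of expected counts (left) and of TPM (right). Bars are means over 3 libraries with SD, and points are replicates. Protein-coding genes hold 66.7% of counts and small noncoding RNA genes 57.4% of TPM.

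Markers of macrophages were all present. All 17 reached a TPM of at least 1 in every library, with a median over markers of 67.7 ± 13.2 (SD, n = 3), Adgre1, which encodes F4/80, at 708 ± 128 and the scavenger receptor gene Msr1 at 267 ± 79.7. Of 79 markers in the 10 lists of other cell types, 6 reached that level and 32 had no count in any library, and with the read-based quantification 14 reached it. The 6 were the endothelial genes Vwf at 15.7 ± 6.22 and Kdr at 7.39 ± 1.80, the erythroid Alas2 at 4.20 ± 1.47, the B cell Cd22 at 3.45 ± 1.04 and the T cell Cd28 at 1.30 ± 0.26 and Cd5 at 1.16 ± 0.19. The other 7 erythroid markers, which include 4 haemoglobin genes, had no counts.

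The highest remaining markers were low in the other lists. For dendritic cells these were Zbtb46 at 1.05 ± 0.45 and Ccr9 at 0.80 ± 0.29, for megakaryocytes Itga2b at 0.87 ± 0.62 and Gp1ba at 0.44 ± 0.28, and for fibroblasts Pdgfrb at 0.91 ± 0.28 and Col1a1 at 0.29 ± 0.26. For neutrophils they were S100a9 at 0.25 ± 0.43 and Ngp at 0.23 ± 0.11, and for B cells Cd79a followed Cd22 at 0.20 ± 0.26. Ncr1 at 0.02 ± 0.035 was the only natural killer cell marker with a count, and for mast cells and basophils Ms4a2 stood at 0.047 ± 0.040 and Cpa3 at 0.017 ± 0.029.

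Replicate 1 stood apart from the other libraries. Across the 9245 expressed protein-coding genes, Pearson's r of log2(TPM + 0.1) was 0.948 between replicates 1 and 2, 0.946 between 1 and 3, and 0.978 between 2 and 3. These are correlations across genes, which are not independent replicates. Spearman's rho was 0.946, 0.942 and 0.978. The biological coefficient of variation from edgeR was 26.3% over 13301 genes and 15.6% without replicate 1. All 3 pairs differed by more than sampling noise, with chi-square per degree of freedom between 22.2 and 78.2, so no library had been deposited again under another name.

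Inflammatory genes varied more between replicates than other genes of the same level. The median SD of log2 CPM was 0.53 for chemokines, 0.43 for feedback regulators, 0.41 for host defence genes, 0.38 for cytokines and 0.33 for interferon-stimulated genes. Between 98.9% and 100% of 10000 expression-matched random lists had a lower median SD. Glycolysis genes lay at 97.7%, housekeeping genes at 97.4%, nuclear long noncoding RNAs at 94.2%, immediate early genes at 93.3% and macrophage transcription factors at 90.7%. Alternative activation genes lay at 88.9%, stress response genes at 83.3%, cell cycle genes at 73.0%, sterol genes at 50.2% and Toll-like receptor 4 components at 16.3%. Without replicate 2 the cytokine list fell to 71.8%, and without replicate 1 the feedback regulators fell to 97.35%. Glycolysis genes fell to 68.8% without replicate 2, and housekeeping genes to 3.06% without replicate 1. Lower lists moved as far: without replicate 1, Toll-like receptor 4 components rose to 86.8% and immediate early genes fell to 58.4%. Without replicate 3, sterol genes fell to 5.92%, alternative activation genes to 58.4% and cell cycle genes to 19.1%, and without replicate 1 cell cycle genes rose to 97.9%. The median SD itself also fell without replicate 1, to 0.26 for chemokines, 0.17 for feedback regulators and 0.28 for host defence genes. It was then 0.35 for cytokines and 0.18 for interferon-stimulated genes. Random lists fell as well, from 0.24 to 0.12 for those matched to chemokines.

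The 10 protein-coding genes of highest SD included both inducible Hsp70 genes, Hspa1a (ENSMUSG00000091971.3, chromosome 17, 34969190 to 34972156) and its near-identical neighbour Hspa1b. Their TPM values were 14.5, 1.64 and 1.65 for Hspa1a and 14.4, 2.11 and 1.93 for Hspa1b in replicates 1, 2 and 3. Bbs10 likewise had 16.0, 2.35 and 2.78, and Cebpb, a transcription factor gene of the inflammatory response, had 28.0, 9.64 and 9.36. Atp5k, Sh3bgrl3 and Arfgef3 were also highest in replicate 1. Siglec1 had 61.3, 37.9 and 15.4, Lipg had 8.42, 1.94 and 7.23, and Nos2 was the remaining gene. For fixed lists, replicate 1 was also compared with the mean of the others in TMM-normalised CPM. The median log2 ratio was 0.69 for feedback regulators, 0.68 for host defence genes, 0.55 for glycolysis genes and 0.50 for interferon-stimulated genes. It was 0.49 for cytokines, 0.46 for macrophage markers, 0.40 for housekeeping genes and -0.40 for nuclear long noncoding RNAs. It was -0.015 for 10381 protein-coding genes. Median log2(TPM + 0.1) of the same lists did not rise alike. In replicates 1, 2 and 3 it was 6.23, 5.72 and 5.73 for feedback regulators and 7.40, 7.46 and 7.34 for interferon-stimulated genes. Cytokines had 3.39, 3.28 and 3.90, and housekeeping genes 4.89, 5.45 and 5.09. Among the lists above, only feedback regulators were highest in replicate 1, where the median gene was lowest, at 3.33 against 3.81 and 3.60.

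**Figure D4:**
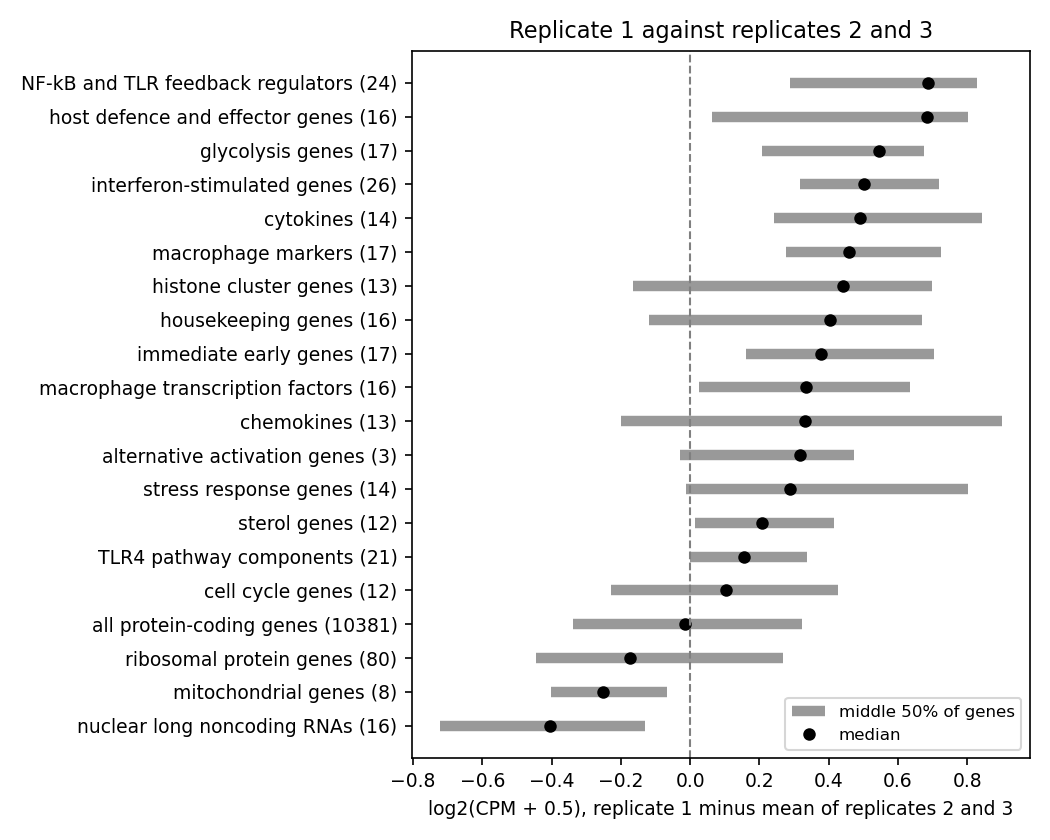
Difference in log2(CPM + 0.5) between replicate 1 and the mean of replicates 2 and 3, by gene set, with the number of genes in brackets. Points are medians and grey bars span the middle 50% of genes. Feedback regulators lie at 0.69 and nuclear long noncoding RNAs at -0.40.

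Isoforms annotated as retaining an intron held a large part of TPM. Over the expressed protein-coding genes they took 38.6% ± 1.32 (SD, n = 3) of TPM, against 48.4% ± 0.16 for protein-coding isoforms, 8.94% ± 0.85 for processed transcripts and 4.03% ± 0.33 for isoforms subject to nonsense-mediated decay. The median gene among 5967 with such an isoform gave it 47.0% ± 1.49. These are shares of TPM, which depend on effective length, and shares of counts by isoform are not given here. Only annotated isoforms entered, so unspliced RNA had no entry of its own. Shares differed widely between single genes picked after their values were seen. Tnip3 had 89.2% ± 2.22, Irf7 81.3% ± 2.89 and Nfkb1 77.2% ± 2.00, against 9.49% ± 2.66 for Nfkb2, 4.97% ± 2.13 for Oas2 and 1.76% ± 1.05 for Il1rn.

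Inflammatory lists did not stand apart in this share. The list median was 65.4% for 5 host defence genes, 57.5% for 6 chemokines, 46.5% for 15 interferon-stimulated genes, 41.0% for 18 feedback regulators and 39.6% for 3 cytokines. Of expression-matched random lists, 91.2%, 79.9%, 29.9%, 10.8% and 27.0% had a lower median, in that order. The other lists with at least 3 such genes lay between 42.0% and 80.2%, except alternative activation genes, of which 3 could be measured, at 0.72%. With the read-based quantification that list moved to 25.7%, cell cycle genes from 80.2% to 20.35% and macrophage transcription factors from 55.4% to 18.9%. With 1 replicate left out, interferon-stimulated genes lay between 51.0% and 70.5%. Macrophage transcription factors fell to 28.6% without replicate 2, and without replicate 1 sterol genes fell from 53.1% to 32.15% and Toll-like receptor 4 components from 47.9% to 29.2%. The smallest lists counted, of 3 genes, were admitted after a first run with a minimum of 5 had left cytokines out. The list medians above were taken over each gene's mean of the libraries. Taken within replicates 1, 2 and 3, medians were 49.4%, 53.6% and 52.9% for interferon-stimulated genes, all above 46.5%. For chemokines they were 50.4%, 56.7% and 50.4%, all below 57.5%.

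The authors' pair of transcript quantifications were compared for the same expressed protein-coding genes. Across genes, Pearson's r was 0.954, 0.925 and 0.923 and Spearman's rho 0.956, 0.927 and 0.925 in replicates 1, 2 and 3. The read-based values were 1.36-fold, 1.25-fold and 1.33-fold higher for the median gene. After removing that shift, 524, 909 and 888 of 9245 genes differed by over 2-fold, and 488, 822 and 803 of them were higher in the read-based values. Read-based values put 18581 genes at a TPM of at least 1 in all libraries, against 12031.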

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

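The rows for added control sequences, which no comparison used, held signal in each library. All of it lay in 1 of the 97 rows, that of the bacteriophage phiX174 genome, a control often loaded with sequencing libraries. It took 1.86% (Wilson 95% interval 1.86 to 1.87) of counts in replicate 1, 0.39% (0.387 to 0.393) in replicate 2 and 0.52% (0.515 to 0.522) in replicate 3, where 0 counts would allow up to 2.9e-05%, 1.7e-05% and 1.7e-05%. The 96 rows of the ERCC set of spike-in RNAs had 0 counts in every library. The phiX174 length and effective length in each library imply mean fragment lengths of 151, 258 and 252 bases in replicates 1, 2 and 3.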

How the results depend on the processing

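Of the values recomputed under an alternative, 309 kept their direction, their side of the threshold or their value within the spread. Another 77 moved further, 6 became weaker, 5 stronger and 2 reversed. These counts do not measure robustness. Leaving out a replicate could not move a mean class share, list level or list difference past its SD, so those values had to count as kept. Percentiles counted as kept if they crossed no limit, as for variability of housekeeping genes, at 97.4 and 3.06 without replicate 1. Interferon-stimulated genes stayed the highest list in every setting, and the order of the 15 lists kept a rank correlation between 0.829 and 1, although with expressed members only cell cycle genes became the lowest. Shares of TPM, CPM, rescaling and expressed members differ by construction, since they change the scale or the genes counted, and for the other alternatives the cause was not tested. With 0 counts at Lif and Mmp9 in at least 1 library, depth limits the lowest values, and without a replicate only 2 libraries remain.

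A TPM threshold of 5 left 7266 genes, 6119 protein-coding and 377 long noncoding, and the read-based quantification gave 18581 genes and 2992 long noncoding. At a TPM threshold of 0.5, dendritic cells and fibroblasts had 1 marker each. Shares of TPM, in percent, were 29.1 for other protein-coding genes, 10.1 for long noncoding RNA genes, 57.4 for small noncoding RNA genes, 1.09 for ribosomal RNA genes, 0.0747 for mitochondrial genes, 0.228 for ribosomal protein genes and 0.0117 for histone cluster genes. Without the ribosomal RNA locus genes, chosen after seeing the data, count shares in percent were 78.0 for other protein-coding genes, 15.1 for long noncoding RNA genes, 6.4e-05 for ribosomal RNA genes, 0.0671 for mitochondrial genes, 0.173 for ribosomal protein genes and 0.00759 for histone cluster genes.

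List levels (log2) with rescaled TPM were 4.83 for cytokines, 5.58 for chemokines, 8.72 for interferon-stimulated genes, 7.21 for feedback regulators, 3.55 for immediate early genes, 6.34 for host defence genes, 5.86 for TLR4 components, 5.61 for macrophage factors, 0.075 for alternative activation genes, 5.99 for glycolysis genes, 6.20 for sterol genes, 1.37 for cell cycle genes, 4.83 for stress response genes, 6.65 for nuclear RNAs and 6.46 for housekeeping genes. With CPM they were 4.18 for cytokines, 8.27 for interferon-stimulated genes, 6.96 for feedback regulators, 3.22 for immediate early genes, 5.69 for TLR4 components, 4.91 for macrophage factors, 5.64 for glycolysis genes, 5.91 for sterol genes, 0.67 for cell cycle genes, 4.39 for stress response genes, 6.93 for nuclear RNAs and 5.87 for housekeeping genes. With expressed members only they were 4.96 for cytokines, 5.57 for chemokines, 3.17 for immediate early genes, 6.05 for host defence genes, 5.17 for macrophage factors, 3.54 for alternative activation genes, 1.96 for cell cycle genes and 6.20 for nuclear RNAs. With the read-based quantification they were 7.497 for interferon-stimulated genes, 4.85 for TLR4 components, 5.04 for glycolysis genes, 5.21 for sterol genes, 1.33 for cell cycle genes and 5.84 for nuclear RNAs, and with a pseudocount of 1 they were 0.48 for alternative activation genes and 1.01 for cell cycle genes.

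Differences between lists with expressed members only were -0.93 for cytokines minus feedback regulators, 0.61 for chemokines minus cytokines, 2.44 for interferon-stimulated genes minus cytokines, 1.09 for host defence genes minus cytokines, -2.73 for immediate early genes minus feedback regulators and 1.06 for nuclear RNAs minus housekeeping genes. With means over members they were -2.89 for cytokines minus feedback regulators, 0.26 for chemokines minus cytokines, 4.38 for interferon-stimulated genes minus cytokines, 0.69 for host defence genes minus cytokines and -0.20 for nuclear RNAs minus housekeeping genes, the last reversed. With CPM they were -0.016 for chemokines minus cytokines and 1.06 for nuclear RNAs minus housekeeping genes, the first reversed, and the read-based quantification gave 0.63 for nuclear RNAs minus housekeeping genes.

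Without replicate 1, 2 or 3 in turn, the biological coefficient of variation ran from 15.6 to 30.3% and the mean correlation from 0.946 to 0.978. The variability percentile ran from 71.76 to 99.98 for cytokines, from 97.35 to 100 for feedback regulators, from 68.76 to 99.1 for glycolysis genes, from 19.07 to 97.89 for cell cycle genes, from 84.31 to 98.15 for nuclear RNAs, and from 3.06 to 99.65 for housekeeping genes. With a prior count of 2 glycolysis genes lay at 97.38, and with DESeq2 size factors housekeeping genes lay at 97.66. Alternative activation genes lay at the 25.7th percentile of retained intron share with the read-based quantification.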

Other observations

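The tests on replicate 1 and on genes found by only 1 quantification were chosen after these patterns were seen, and the one on other cell types after its own values were seen.

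Sex-linked genes and microRNA host genes were chosen after their values were seen. Xist had a TPM of 577, 911 and 797 in replicates 1, 2 and 3, while the Y-linked Ddx3y, Eif2s3y and Uty had 0 counts and Kdm5d had 1 count in each library. In the read-based values of the same libraries Uty stood at 2.97, 14.5 and 11.7 and Kdm5d at 5.396, 6.76 and 6.49. Ddx3y was lower there, at 0.62, 1.22 and 1.46, as was Eif2s3y, at 0.49, 0.91 and 0.94. Among host genes of microRNAs, Mir155hg stood at 253 ± 91.0 (SD, n = 3), Mir22hg at 129 ± 27.9 and Mir17hg at 12.7 ± 7.36.

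Replicate 1 differed across protein-coding genes at large. In TMM-normalised CPM, 367 of 10381, the inflammatory lists included, were over 2-fold higher than the mean of replicates 2 and 3. Another 204 were over 2-fold lower, while 166 differed by over 2-fold between replicates 2 and 3. Genes lower in replicate 1, picked for that, included Rims3, with TPM of 1.48, 8.84 and 5.13, Bmp1 with 8.81, 29.9 and 29.7, and Utp20 with 3.50, 8.78 and 11.7.

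No biological explanation was tested for the genes found by only 1 quantification. Of protein-coding genes, 902 had a read-based TPM of at least 1 in every library but an alignment-based TPM below 0.1, Cd3d at 14.1 against 0.017 and Uty among them, and 11 showed the reverse. An expressed gene on the opposite strand overlapped 29 of the 902, 3.22% against 1.33% of 5475 genes found by neither (Fisher's exact test, p = 1.4e-04), and one on the same strand 1.55% (p = 0.25). Opposite-strand reads needed over 50% to overlap by the prediction written before the test, and the upper end of the interval was 4.58%. A rule added after these values were seen took those 29 genes as the most that such reads account for. The overlap covered only annotated, expressed genes, so unannotated transcripts and genes of lower level were not seen. It therefore sets no upper limit. The excess of overlapping genes also missed the condition first written for setting such reads aside, and they remain open. The 29 count genes and not signal. Gm17374 and Gm17571, picked for mean read-based TPM values of 737 and 682, were among the overlapping genes, while Gm47283, at 752, was not. A stretch of 31 bases shared with a transcript of an expressed gene was found in 81.1% of 901 genes, against 11.5% of 901 length-matched genes found by neither (Fisher's exact test, p = 2.1e-212), so shared sequence may be a source of these values, though the typical gene shared only 1.00% of its stretches. Only 1 in 8 stretches was searched, so both shares may be too low. Both strands were treated as one, so overlapping transcripts on opposite strands would also count as shared.

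The labels name no biological explanation for the difference of replicate 1, and none beyond RNA of another cell type was tested. That explanation remains open. In replicate 1 at most 33.3% of the markers of any such type reached a TPM of 1. The read-based endothelial share was 50% in all libraries. By alignment-based values only megakaryocyte markers had their highest share in replicate 1 (16.7% against 0% and 0%). Their read-based share ran the other way, at 16.7% against 33.3% and 33.3%. Median log2 ratios were 0.68 for 3 endothelial and 0.16 for 3 dendritic cell markers. Gene length also remains open: Spearman's rho across 10381 genes between effective length and the log2 ratio of replicate 1 to the others was -0.15, between the sizes of 0.1 and 0.2 written down as limits, against 0.028 for replicate 2 to 3. Carried-over cytoplasmic RNA also remains open, with median log2 ratios of -0.17 for ribosomal protein genes and -0.25 for 8 mitochondrial genes, the latter just past the limit for setting it aside. The mitochondrial value rests on alignment-based counts, which nearly lack mt-Atp6. Outside the written prediction, medians in TMM-normalised CPM were 0.40 for housekeeping genes and -0.40 for nuclear long noncoding RNAs. The retained intron share of the median gene was 45.4% in replicate 1, against 48.2% and 47.6% in replicates 2 and 3. Whether these values reflect cytoplasmic RNA was not tested. RNA input and fragment length differed between the same libraries and could not be separated from the replicate.

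RNA being made on chromatin could carry introns, and genes induced by Lipid A might then show a high share of isoforms with a retained intron. The prediction, written before the shares were computed, put the cytokine, chemokine and interferon lists each in the top 2.5% of expression-matched lists. None did: cytokines lay at the 27.0th percentile, interferon-stimulated genes at the 29.9th and chemokines at the 79.9th. The condition written for setting the idea aside was 1 list below 50, and cytokines stayed there in every setting, a demand added after the values were seen, while the 15 interferon-stimulated genes lay at 51.0 to 70.5 with 1 replicate left out. Among the genes measured, the 3 lists thus did not each hold a high share. This rests on 3 cytokine genes admitted after the first run. Under a limit of 2.5, also tried after the values were seen, the idea would stay open. Only 3 cytokines, 6 chemokines and 15 interferon-stimulated genes were expressed with such an annotated isoform and entered. The matched lists were chromatin RNA as well, and induction was not measured. The test therefore cannot decide whether new transcripts of induced genes were incompletely spliced.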
